A study of Homo sapiens with 18 samples.

How the data were processed

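Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in primary human hepatic stellate cells, the liver cells that make scar matrix once activated. Per the labels, the cells were grown for 72 hours on cellular microarrays, that is, small printed spots of defined extracellular matrix on a gel of set stiffness. The 18 libraries formed 6 groups of 3. C1FN stood for collagen 1 with fibronectin, C4TC for collagen 4 with tenascin C, and FNLN for fibronectin with laminin, each at 25 kPa and at 1 kPa. Libraries were made from isolated nuclei with a commercial ATAC-seq kit, per the labels' protocols.

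The deposited files held whole-number counts per genomic region, not normalised, with the same 499100 regions in every file. The build was hg19, per the submitters' processing notes, and regions on chromosome 1 reached position 249219716, which lies inside that build's chromosome 1. The aligner, the peak caller, the counting tool, any shift of reads for the transposase, the removal of duplicate reads and the way the region list was made are not given in the sources used here. Regions were 150 to 3806 bp wide (median 635) and many overlapped, so that a read could be counted in several of them. Regions that overlapped were merged into 111294 separate loci, with a median of 5 and at most 16 regions each, and 14227 loci held 1 region. A count of regions therefore repeats the same stretch of DNA several times, and counts of loci stand beside it. Whether the first base is counted as 0 or 1 is not given in the sources used here, and coordinates are printed as the files give them.

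Total counts over all regions ran from 82.0 M to 229.53 M counts per library. These totals hold reads more than once. With the region of highest mean count standing for each locus, totals ran from 15.8 M to 43.6 M. Every named region had at least 16 counts in every library. Within each group, no 2 libraries agreed within sampling noise: the chi-square per degree of freedom between pairs, over loci with at least 20 counts, ran from 2.49 to 7.17, so that all 18 were counted as separate samples. The labels do not say whether replicates came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

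Each comparison was fitted with edgeR 4.0.16 (R 4.3.3) on the counts of all 18 libraries in 1 model with 6 group means and 12 residual degrees of freedom. TMM factors, filterByExpr and the robust quasi-likelihood test were used, with Benjamini-Hochberg adjustment over the 499077 regions tested and a threshold of 0.05. Positive log2 differences mean higher counts at 25 kPa, or in the first-named matrix pair. The standard error of a log2 difference was its size divided by the square root of the quasi-likelihood F. The same fit on 1 region per locus (111280 tested) gave counts of loci, effect sizes and agreement between comparisons; it was added after the overlaps had been seen. CPM are relative to a library's TMM-scaled total over all regions, so they are low in absolute terms, and log2 CPM used a prior count of 2. Library measures were compared with exact two-sided permutation tests that exchanged stiffness labels within each matrix pair (8000 arrangements). These tests, and the edgeR average over matrix pairs, treat the libraries as separate. Same-numbered libraries deviated together within a stiffness, most evenly at 1 kPa. If such sets are the true replicates, these p-values are too small. For matrix comparisons within a stiffness the effect would be the reverse. Deviations shared by a set stay in the error of a model without a replicate term, so those p-values may be too large.

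Regions were named by a rule set before the data were examined: past the threshold, above the median abundance, and with the 3 libraries at 25 kPa not overlapping the 3 at 1 kPa within any matrix pair compared. The 5 with the largest difference in each direction were taken, 1 per locus. Where nothing passed, the 3 smallest p in each direction were taken and are described as not passing. Regions on the sex chromosomes were left out of naming. An annotation of hg19 was not used here, so regions carry no gene names, and coordinates were not converted. For that reason the gene list tests and the promoter share of counts that had been planned were not run.

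Replicate numbers come from the sample titles. Deviations of log2 CPM from the group means were correlated between same-numbered libraries of different groups. Over all 45 such pairs r ran from -0.325 to 0.495, so the numbers did not pair the libraries over the whole design. Every one of the 3 pairs lay above 0.1 for stiffness in C1FN (0.133 to 0.20), for FNLN against C4TC at 25 kPa (0.118 to 0.303) and for the 3 matrix comparisons at 1 kPa (lowest 0.111). The model of every comparison held no replicate term, and the block on replicate numbers was fitted as an alternative; the block within each stiffness was added after these correlations had been seen.

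The pipeline was tested on simulated counts drawn from the real abundances, library sizes and spread, with 67 loci changed 1.3-fold, 67 changed 1.5-fold and 66 changed 2-fold among 111280. Each library was drawn separately, with 1 region per locus, so the simulated data held no sets of same-numbered libraries and no overlapping regions. The fitted quasi-likelihood spread scaled only the variance beyond counting noise, not the whole variance as in the test. Few loci were changed, whereas 39.78% of loci were called in the real average over matrix pairs. The adjustment was therefore stricter in the simulation, and its recovered shares do not carry over to that average. For stiffness over all matrix pairs it recovered 28.4% of 1.3-fold, 58.2% of 1.5-fold and 87.9% of 2-fold changes, with 8 false calls among 124. For FNLN against C1FN at 1 kPa it recovered 1.49%, 17.9% and 53.0%, with 6 false calls among 54.

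Alternatives were median-of-ratios factors, total counts only, loess offsets that follow abundance, no filter, a replicate block, DESeq2 1.42.0, a fit of only the groups compared, and leaving out each library in turn. Alternatives added after the data had been seen were 1 region per locus, a replicate block within each stiffness, the same block without library 1 of C1FN at 1 kPa, leaving out the 3 libraries numbered 2 at 1 kPa, and matrix comparisons over both stiffnesses. Figures were drawn with matplotlib 3.10.9.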

Results

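Accessibility was measured in primary human hepatic stellate cells after 72 hours on 3 pairs of extracellular matrix proteins at 2 substrate stiffnesses, with 3 libraries in each of 6 groups. The pairs were collagen 1 with fibronectin (C1FN), collagen 4 with tenascin C (C4TC) and fibronectin with laminin (FNLN). The design asks how matrix composition and stiffness each relate to chromatin accessibility, and whether they act together. Counts were given for 499100 partly overlapping regions, which merged into 111294 loci. Library totals were 188.6 ± 31.6 M counts at 25 kPa and 132.2 ± 36.1 M counts at 1 kPa (mean ± SD, n = 9 each), a difference of 56.4 M (p = 0.0045, exact two-sided permutation test within matrix pairs). The ranges overlapped, from 132.74 to 229.53 M at 25 kPa and from 82.0 to 187.45 M at 1 kPa.

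Stiffness separated the libraries. The first principal component of log2 CPM over loci held 45.3% of the variance and placed the 9 libraries at 25 kPa between 35.3 and 109.3, and the 9 at 1 kPa between -116.8 and -36.8 (p = 0.00025, exact permutation test, the smallest p that the 8000 arrangements allow). The second component held 10.8% and set the 3 libraries numbered 2 at 1 kPa (-48.7 to -63.2) apart from the other 1 kPa libraries (4.76 to 95.1).

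**Figure D1:**
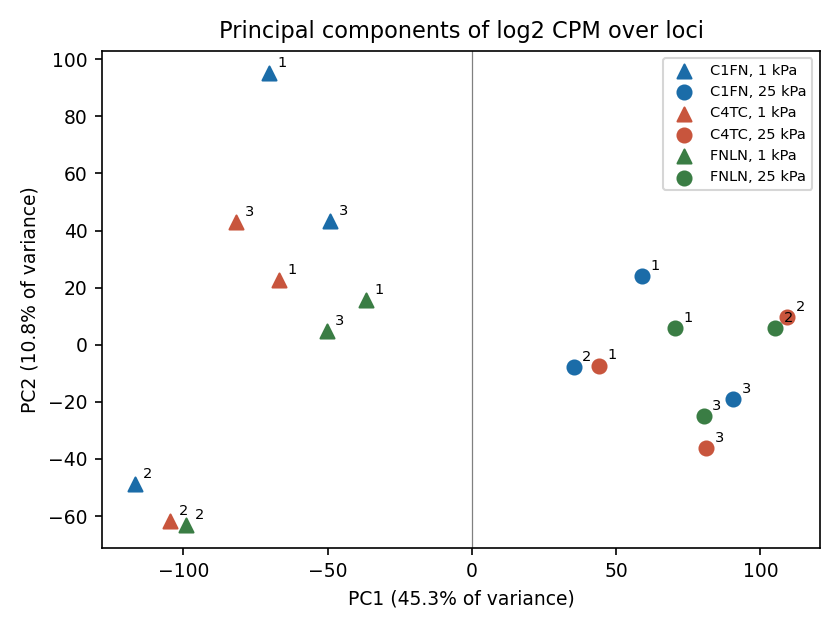
First and second principal components of log2 CPM over loci, 1 point per library, with colour for the matrix pair, circles for 25 kPa, triangles for 1 kPa and the replicate number beside each point. All 25 kPa libraries lie at 35.3 or above on the first component and all 1 kPa libraries at -36.8 or below, with the 3 matrix pairs mixed within each side.

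Averaged over the 3 matrix pairs, 46820 loci (42.1% of those tested) held at least 1 region that differed between 25 kPa and 1 kPa. This average took the 9 libraries of a stiffness as separate samples. If sets of same-numbered libraries are the true replicates, its errors and p-values are too small and its counts too large. Among regions above the median abundance whose libraries did not overlap between stiffnesses, to which the regions named here and for each matrix pair were limited, the largest increases at 25 kPa lay near the end of the long arm of chromosome 5. Region chr5:180528676-180529389 (hg19) rose 3.35-fold, from 1.07 ± 0.24 CPM at 1 kPa to 3.54 ± 0.40 CPM at 25 kPa (mean ± SD, n = 9 each), a log2 difference of 1.74 ± 0.099 (SE; edgeR adjusted p = 6.71e-12). Its neighbour chr5:180523923-180524760 rose 3.14-fold and chr5:180600564-180601267 rose 2.90-fold. Regions chr14:80010972-80011428 and chr6:28770371-28770827 rose 3.03-fold and 3.01-fold. The largest decreases exceeded them. Region chr1:66861012-66861860 was 9.0-fold lower at 25 kPa, at 0.226 ± 0.142 CPM against 1.91 ± 0.52 CPM at 1 kPa, a log2 difference of -3.17 ± 0.257 (SE; edgeR adjusted p = 1.34e-07). Regions chr5:150484327-150484830 (6.54-fold lower), chr7:34182850-34183632 (6.52-fold) and chr11:102821270-102821997 (6.45-fold) followed, each with an adjusted p of 4.13e-07 or less. Region chr6:160097618-160099995, the most accessible of the named regions that fell, was 6.86-fold lower with a wider error, at 1.29 ± 0.76 CPM against 8.53 ± 4.13 CPM (adjusted p = 0.000206).

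**Figure D2:**
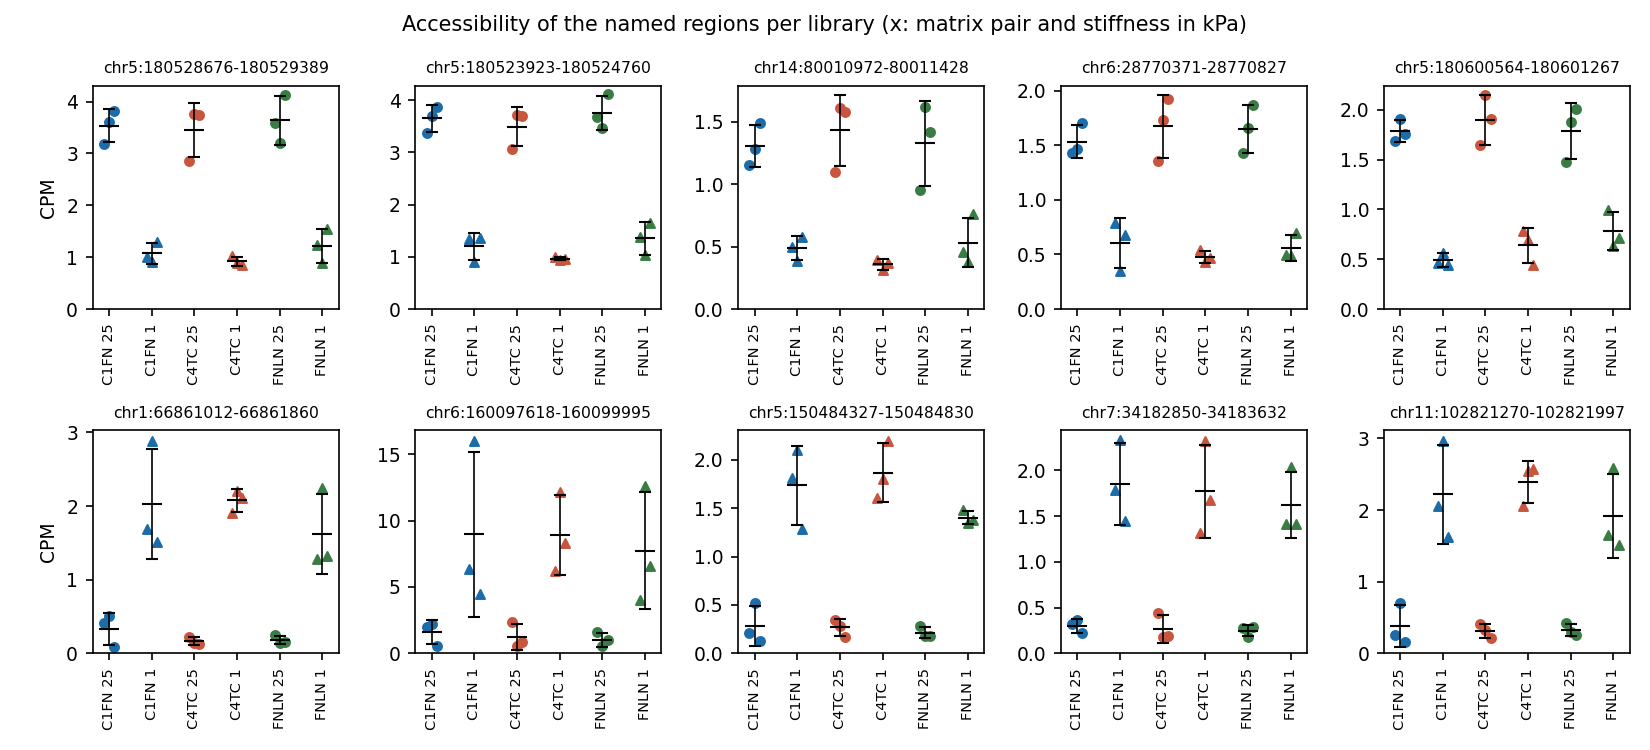
CPM of the 10 regions with the largest named differences between stiffnesses, per library, by matrix pair and stiffness in kPa; horizontal marks and bars give the mean and SD of 3 libraries. The upper row shows the 5 regions that were higher at 25 kPa, such as chr5:180528676-180529389 at 3.54 against 1.07 CPM, and the lower row the 5 that were lower, such as chr1:66861012-66861860 at 0.226 against 1.91 CPM.

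By the edgeR quasi-likelihood test, 198392 of 499077 regions passed the threshold in the average over matrix pairs, 90540 of them higher and 107852 lower at 25 kPa. With 1 region per locus, 44264 of 111280 loci passed, 20420 higher and 23844 lower. The median absolute log2 difference over all loci was 0.217, against a median SE of 0.122. Large changes went mostly one way: 5028 loci were called at more than 2-fold lower and 444 at more than 2-fold higher, and 529 against 0 at more than 4-fold. The ratio of decreases to increases beyond 2-fold among regions was 11.3, and was 5.7 with loess offsets and 22.3 without the 3 libraries numbered 2 at 1 kPa.

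On C1FN, 15636 loci held a region that differed between stiffnesses. Within the same limits, the regions with the largest increases at 25 kPa were chr5:180600564-180601267 (log2 difference 1.85 ± 0.197 SE), chr5:180528676-180529389 (1.74), chr5:180523900-180524727 (1.63), chr16:3241438-3241731 (1.59) and chr6:28715447-28715914 (1.54). The largest decreases were at chr1:66860901-66861776 (-2.63 ± 0.42 SE), chr1:206973734-206974757 (-2.63), chr7:34182850-34183632 (-2.62), chr5:150484327-150484830 (-2.58) and chr11:102821270-102822015 (-2.54). The adjusted p of these 10 regions was 0.00103 or less. In all, 60576 regions passed, 19529 higher and 41047 lower. The count for stiffness in C1FN was 26945 without library 3 at 25 kPa, 32574 without library 2 at 1 kPa, and 38623 without the 3 libraries numbered 2 at 1 kPa. Of the regions named, chr1:66860901-66861776 and chr11:102821270-102822015 missed the threshold when only the C1FN groups were fitted.

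On C4TC, 20396 loci held a called region. Within the same limits, increases were led by chr14:80010972-80011428 (log2 difference 2.02 ± 0.248 SE), chr5:180528676-180529389 (1.91), chr5:180523923-180524760 (1.86), chr6:28770358-28770820 (1.82) and chr16:3241438-3241731 (1.80). Decreases were led by chr1:66861012-66861860, which was 12.8-fold lower at 25 kPa (-3.68 ± 0.462 SE, adjusted p = 7.51e-05), followed by chr6:44702966-44703845 (8.0-fold), chr11:102821343-102821860 (7.94-fold), chr15:80935765-80936458 (7.79-fold) and chr6:160097663-160099967 (7.38-fold, adjusted p = 0.0183). The last region missed the threshold when library 2 at either stiffness or library 3 at 25 kPa was left out, and when only the C4TC groups were fitted. In all, 82242 regions passed, 30074 higher and 52168 lower, and for stiffness in C4TC 48703 and 51072 passed without library 2 at 25 kPa and at 1 kPa.

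On FNLN, 15929 loci held a called region. Within the same limits, increases were led by chr5:180528676-180529389 (log2 difference 1.59 ± 0.167 SE), chr6:28770371-28770827 (1.58), chr5:180523923-180524760 (1.48), chr5:10485209-10485947 (1.42) and chr1:147736906-147737614 (1.42). Decreases were led by chr1:66861012-66861860 (9.2-fold), by the neighbours chr4:74609536-74609834 (8.94-fold) and chr4:74607623-74608816 (8.78-fold), and by chr6:160097618-160099995 (7.69-fold) and chr7:134144792-134145133 (7.39-fold). Of these, chr6:160097618-160099995 and chr4:74607623-74608816 missed the threshold when FNLN library 2 at either stiffness was left out, and the first of them also without library 3 at 25 kPa, without the 3 libraries numbered 2 at 1 kPa, and when only the FNLN groups were fitted. In all, 62703 regions passed, 18420 higher and 44283 lower. The count for stiffness in FNLN was 27585 without library 2 at 1 kPa, 37509 without library 2 at 25 kPa, and 35850 without the 3 libraries numbered 2 at 1 kPa.

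The stiffness difference was shared by the matrix pairs, whose comparisons have no library in common. The comparisons are still not independent, because same-numbered libraries of different pairs deviated together at 1 kPa (r = 0.111 to 0.495). Separate handling of the stiffnesses would also recur on every pair. Across 111280 loci, which are not independent replicates, the log2 differences correlated at r = 0.82 between C1FN and C4TC, 0.80 between C1FN and FNLN, and 0.844 between C4TC and FNLN. With 1 region per locus, 1796 loci were higher at 25 kPa on all 3 pairs and 6196 were lower on all 3, against 10.6 and 93.5 for independent lists of the same lengths. No locus was called in opposite directions on any 2 pairs. Region chr5:180528676-180529389 rose by 1.74, 1.91 and 1.59 on the log2 scale on C1FN, C4TC and FNLN, and chr1:66861012-66861860 changed by -2.63, -3.68 and -3.20.

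**Figure D3:**
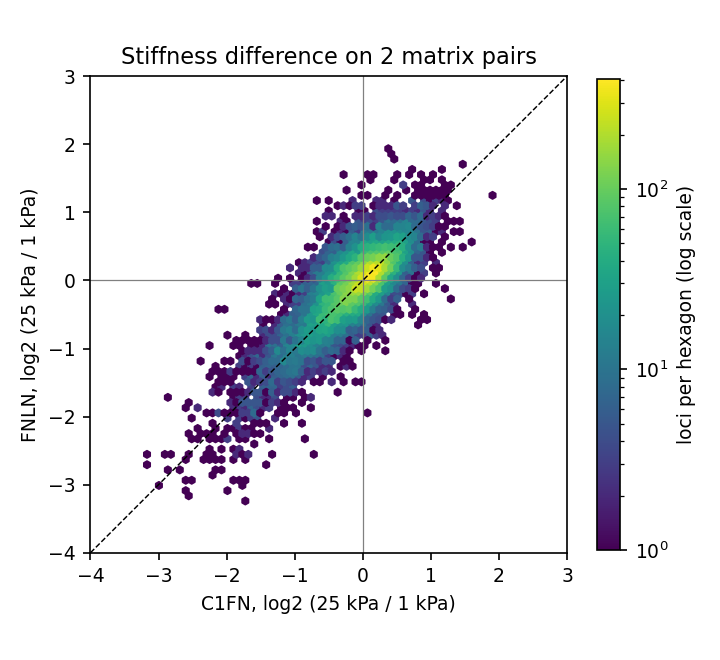
Log2 difference between 25 kPa and 1 kPa on C1FN (x) against FNLN (y), for a random sample of loci drawn as hexagons coloured by their number of loci on a log scale; the dashed line marks equal differences. The cloud runs along the line (r = 0.80 over all loci) and reaches farther into decreases than into increases.

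Whether the stiffness difference was unequal among the matrix pairs was tested as an interaction. No region passed in edgeR (5924 of 499077 at an unadjusted p under 0.05) or in DESeq2. With 1 region per locus, 1547 of 111280 loci had such a p, against 5564 by chance alone. The test may therefore have been conservative. Among regions above the median abundance, those nearest to the threshold were chr3:183951869-183952420, chr17:59433774-59434390 and chr12:107730960-107731818, which did not pass (edgeR adjusted p = 1 for each). At a typical locus, the unadjusted 95% interval of a difference between stiffness effects was 0.647 to 0.655 either side of its estimate on the log2 scale. A call also had to pass the adjustment over all regions. Unequal effects of that size or smaller were thus mostly not detectable at this number of libraries, and larger ones could be missed too.

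The matrix pairs differed less. At 25 kPa no region passed for C4TC against C1FN, FNLN against C1FN or FNLN against C4TC in edgeR or DESeq2. In edgeR, 11215, 11005 and 4321 regions had an unadjusted p under 0.05. With 1 region per locus, 2759, 2769 and 1213 of 111280 loci had such a p, against 5564 by chance alone. Small p were thus too few, the test may have been conservative, and 0 calls do not show that the pairs were alike. Deviations shared by same-numbered libraries, where present, stayed in the error of this model. Whether they account for the few small p was not tested. Median absolute log2 differences were 0.12, 0.118 and 0.0958, below the median SE of 0.206 to 0.207. Among regions above the median abundance outside the sex chromosomes, the smallest p belonged to chr1:177882737-177884088, lower on C4TC than on C1FN by a log2 difference of -0.56 ± 0.137 (SE), to chr10:78641179-78642248, at -0.67 ± 0.155 on FNLN against C1FN, and to chr8:144594753-144595366, at 0.52 ± 0.141 on FNLN against C4TC; all 3 had an adjusted p of 1.

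At 1 kPa the same comparisons also gave 0 regions in edgeR, with 11660, 19562 and 11411 at an unadjusted p under 0.05. With 1 region per locus these counts were 2972, 5326 and 2713, also below the 5564 of chance alone, although FNLN against C1FN came close to it. Over both stiffnesses, FNLN against C1FN had 5914 such loci. Its log2 differences at 25 kPa and 1 kPa correlated at r = 0.163 across loci. The values were 0.0799 for C4TC against C1FN and 0.00788 for FNLN against C4TC. Loci are not independent, and these correlations were not tested. The smallest p by the same rule were at chr20:50044732-50045888 for C4TC against C1FN (-0.59 ± 0.136 SE), at chr19:16439945-16440210 for FNLN against C1FN (0.91 ± 0.165) and at chr16:3241438-3241731 for FNLN against C4TC (0.77 ± 0.181), none of which passed in edgeR (adjusted p = 1). DESeq2 called the chr19 region alone (adjusted p = 0.0475) and none in the other comparisons.

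FNLN against C1FN was the matrix comparison in which other models made calls. With a replicate block within each stiffness, added after the data had been seen, 63 regions in 18 loci passed for FNLN vs C1FN at 1 kPa and 5 regions in 1 locus at 25 kPa. Of the 17 loci at 1 kPa outside the sex chromosomes, 8 were higher and 9 lower on FNLN. The locus of chr11:117079379-117081930 was the one called at both stiffnesses, and the region was higher on FNLN by 0.66 ± 0.0927 (SE, adjusted p = 0.00535) at 1 kPa and by 0.62 ± 0.0895 (adjusted p = 0.00951) at 25 kPa on the log2 scale. The largest increases at 1 kPa were at chr19:16439945-16440210 (0.93, adjusted p = 0.00597), the region that DESeq2 also called, and chr7:5562346-5563469 (0.76), and the largest decreases at chr9:68490907-68491506 (-1.30) and chr6:57566467-57567426 (-1.23). The chr9 region lies in the 1-Mb stretch from 68 Mb that was also the lowest for stiffness (-0.93). Reads shared between near-identical sequences may add to such decreases, which was not tested. For FNLN vs C1FN over both stiffnesses, 103 regions passed with the block, 14 passed in DESeq2 and 0 in the unblocked edgeR fit. C1FN library 1 at 1 kPa had the lowest share of counts in the most accessible decile of loci (45.6%, against 48.3% or more in the other 17). Without it the blocked fit called 0 regions at either stiffness and 9 over both, all of them higher on FNLN and in 2 loci of chromosome 11, that of chr11:117079379-117081930 and chr11:117005733-117007537 (0.56 ± 0.0834 SE, adjusted p = 0.0192). The 25 kPa comparison does not contain this library, yet its call was lost too. No other library was left out of the blocked fit. The lost calls therefore cannot be tied to this library or to its share of counts. The regions named for FNLN against C1FN in these fits were picked after their values were seen.

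Accessible loci and less accessible loci were called higher and lower at 25 kPa in different proportions. In the most accessible decile 37.9% of loci were higher and 8.11% lower at 25 kPa, while in the least accessible decile 7.23% were higher and 21.8% lower. The median log2 difference ran from -0.0975 in the second decile to 0.111 in the tenth. Unequal signal to background between the stiffnesses could give such a trend with abundance as well. The decile shares were not recomputed with loess offsets, so the 2 cannot be told apart here. The top decile by mean raw count held 51.07% ± 0.92 of the counts over loci at 25 kPa and 49.15% ± 1.48 at 1 kPa (SD, n = 9 each, p = 0.00025, exact permutation test, the smallest the arrangements allow). This decile was chosen on the same libraries, in which the deeper 25 kPa libraries weigh more. The choice therefore favours a higher share at 25 kPa, by an amount that was not tested. The share of called loci also varied by chromosome. On chromosome 19, 23.7% of loci were higher and 12.1% lower at 25 kPa, while the other autosomes ranged from 16.9% to 21.1% higher and from 16.9% to 24.7% lower. These shares were not tested.

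**Figure D4:**
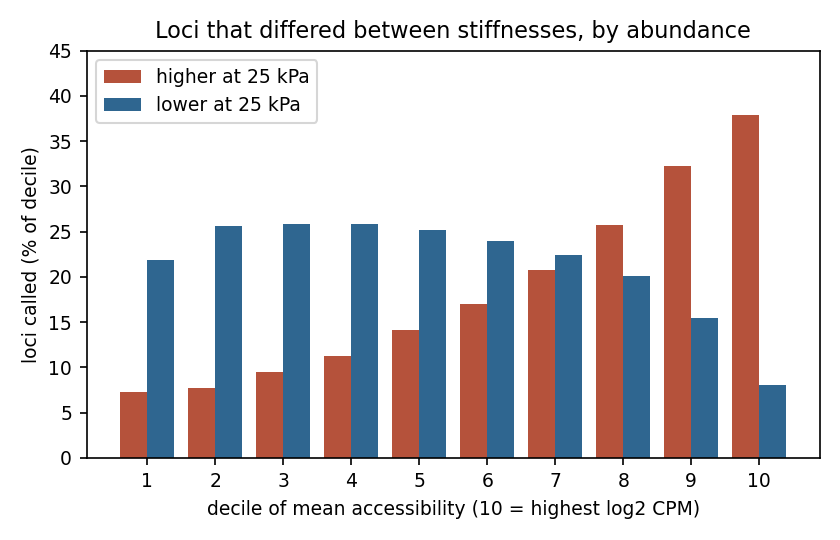
Percent of loci called higher (red) and lower (blue) at 25 kPa in each decile of mean accessibility, averaged over the matrix pairs, 1 region per locus. The share called higher goes from 7.23% in the lowest decile to 37.9% in the highest, and the share called lower from 21.8% to 8.11%.

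Called loci also gathered along the genome. On chromosome 6 between 26 and 29 Mb, 136 of 243 loci were higher at 25 kPa and 6 lower, and the mean log2 difference per 1-Mb stretch was 0.251, 0.411 and 0.424. The stretches on either side averaged -0.131 and -0.316. The stretch of chromosome 5 from 180 Mb, which holds 3 of the named regions, averaged 0.332, with 20 of 37 loci higher and 2 lower. The lowest stretch was chromosome 9 from 68 Mb, at -0.93, with 20 of 25 loci lower and 0 higher. Reads shared between near-identical sequences may add to the lowest stretch, which was not tested. All of these stretches were picked after their values were seen.

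**Figure D5:**
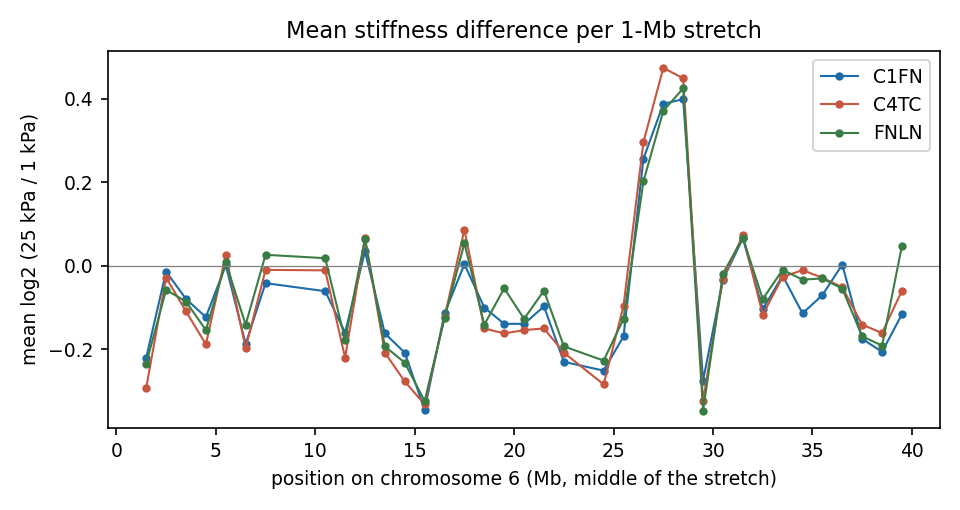
Mean log2 difference between 25 kPa and 1 kPa over the loci of each 1-Mb stretch of chromosome 6 up to 40 Mb, for stretches with at least 20 loci, with 1 line per matrix pair. All 3 lines stand above 0 from 26 to 29 Mb, between 0.202 and 0.474.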

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

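The settings named here as added were chosen after the data had been seen; all others were set before. None of the 40 calls of regions named for stiffness changed direction in the settings in which it was tested; regions named for the matrix comparisons and the interaction were not followed. None of the 4 stiffness counts lost its excess of decreases. For stiffness over all ECM, the average of the matrix pairs, the count of 198392 regions stayed within 1.5 times in every setting that kept all regions (159297 to 206010, the block within each stiffness aside). With 1 region per locus (added), which tests fewer features, 14184, 18579, 14448 and 44264 passed for stiffness in C1FN, stiffness in C4TC, stiffness in FNLN and their average. Leaving out each library gave 26945 to 66217 on C1FN, 48703 to 75526 on C4TC and 27585 to 62230 on FNLN, with fewer samples, and 0 in every matrix comparison and the interaction; the lowest values came without C1FN library 3 and C4TC library 2 at 25 kPa and FNLN library 2 at 1 kPa. Without the 3 libraries numbered 2 at 1 kPa (added), C1FN gave 38623 and FNLN 35850. The replicate block gave 69868, 89449, 69836 and 206010 for the 4 stiffness results and 0 for the matrix comparisons and the interaction; 13 of 18 libraries correlated best with their own number. The replicate block within each stiffness (added) gave 104025, 125537 and 109025 on C1FN, C4TC and FNLN, but stiffness does not vary within its blocks, so it takes the spread between sets out of the error of those counts and informs only the matrix comparisons. It gave 63 for FNLN vs C1FN at 1 kPa and 5 for FNLN vs C1FN at 25 kPa. DESeq2 gave 1 for FNLN vs C1FN at 1 kPa. The cause of these differences was not tested. The 40 calls of named regions were kept with every scaling, without the filter and in DESeq2; 26 of 30 were kept with only the groups compared, 39 of 40 without the libraries numbered 2 at 1 kPa, and 352 of 360 with 1 library left out. No scaling moved the median of all regions by over 0.1. In data simulated at the existing depth and group size, 53.0% of 2-fold changes between FNLN and C1FN at 1 kPa were recovered. Those data held 1 region per locus and no sets of same-numbered libraries, so the real fit over all regions may recover a different share. The gene lists and the promoter share of counts were not run, and settings for other units did not apply.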

Other observations

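The tests on batches, on single libraries and the libraries numbered 2 behind the excess of decreases, and on stretches against shuffled genomes were chosen after the result was seen.

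Neighbouring loci differed between stiffnesses in similar ways. After the median of their abundance class was taken off, the log2 differences of pairs of loci under 5 kb apart correlated at r = 0.32 across 41130 pairs, against 0.0062 with loci shuffled within chromosomes. The correlation was 0.131 from 5 to 20 kb, 0.0623 from 20 to 100 kb and 0.021 from 100 to 500 kb. Over 1941 stretches of 1 Mb with at least 20 loci, the mean differences of C1FN and C4TC correlated at r = 0.908, and 485 stretches averaged above 0. Pairs and stretches are not independent replicates, and no p is given.

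Groupings of the same libraries other than the real one were fitted on 1 region per locus. For stiffness over all matrix pairs, 1 of 60 drawn splits within matrix pairs, the real one, gave 44264 loci, and the highest of the others gave 0. These splits exchanged libraries one by one, although same-numbered libraries deviated together within a stiffness, most evenly at 1 kPa. Moved as whole sets of the same number, the libraries allow only 10 splits, so chance is not excluded at the level of sets. On C1FN, C4TC and FNLN the real splits gave 14184, 18579 and 14448 loci and were the largest, 1 of 10, with 0 as the highest other; 10 splits are too few for a share under 0.05. For the 6 matrix comparisons, where the real split gave 0, all 10 of 10 splits were as large by necessity. The highest other was 12, 1332 and 0 at 25 kPa and 4, 0 and 0 at 1 kPa, for C4TC against C1FN, FNLN against C1FN and FNLN against C4TC. The 1332 loci came when C1FN library 2 was exchanged with FNLN library 1 at 25 kPa. This split was picked as the highest after it was seen, and its cause was not tested. For the interaction, where the real count was also 0, 25 of 25 splits were as large by necessity, with 481 the highest, so nothing follows about chance.

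The difference between stiffnesses could come from the lower depth at 1 kPa. With every library thinned to 15.8 M counts over loci, 39200 loci passed. Of the loci called without thinning, 84.8% were called in the same direction and 0 in the opposite one. This argues against the number of counts by itself. Thinning cannot undo other traits that may go with depth, such as duplicate reads or a library's weight in the region list, and these stay open. The libraries could also have been handled in separate batches by stiffness. Same-numbered libraries deviated together within 1 kPa (median r = 0.207, with 9 of 9 pairs above 0.1). Within 25 kPa they did so less evenly (median r = 0.158, from -0.13 to 0.304, with 6 of 9 pairs above 0.1). Across the stiffnesses they mostly did not (median r = -0.0508), although the 3 pairs within C1FN lay above 0.1 (0.133 to 0.20). Such batches and stiffness cannot be told apart, because the labels used here give no batch; stiffness itself stays open as the biological explanation.

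Decreases beyond 2-fold at 25 kPa outnumbered increases, 16172 against 1428 called regions over all matrix pairs. A trend with abundance from unequal signal to background might produce this. Measured from the median of their own decile, decreases outnumbered increases by at least 2 to 1 in 10 of 10 deciles. The counts went from 1032 against 114 in the lowest decile to 33 against 4 in the highest. These medians lay between -0.0975 and 0.111 and the calls were not refitted. Taking the medians off could therefore hardly change the excess, and this count does not decide the question. Loess offsets, which follow abundance in the fit, lowered the ratio from 11.3 to 5.7 but kept an excess. With each library left out the ratio was at least 8.78, and without the 3 libraries numbered 2 at 1 kPa it was 22.3, so neither accounts for it. Separate handling of the stiffnesses stays open here as well, beside a response of the cells to stiffness.

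Some 1-Mb stretches had a shifted mean, although not every locus in them was called. The 5 highest stretches of C1FN were on chromosome 6 from 27 and 28 Mb, chromosome 5 from 180 Mb, chromosome 19 from 37 Mb and chromosome 8 from 12 Mb; they averaged 0.403 in C4TC and 0.341 in FNLN. The 5 lowest, on chromosome 9 from 68 and 69 Mb, chromosome 4 from 190 and 147 Mb and chromosome 20 from 7 Mb, averaged -0.699 and -0.511. In 1000 shuffled genomes, deviations from the abundance trend changed places in runs of 5 neighbouring loci and the stretches were chosen again in C1FN; this choice alone gave medians of 0.165 and 0.146 for the highest and -0.415 and -0.37 for the lowest. The real values lay beyond at least 99.9% of the shuffles, which argues against the trend and a chance gathering of such runs as the whole cause; a spread that varies with abundance was not kept in place. With 1 of the C1FN libraries left out, the highest stretches kept at least 0.91 of their C1FN difference and the lowest at least 0.785 (without C1FN library 1 at 1 kPa), which argues against a single library as the whole cause. Reads shared between near-identical sequences may add to the lowest stretches, and this was not tested, since no genome was used here.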
